A study of Mus musculus with 12 samples.

How the data were processed

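Polyadenylated RNA was sequenced from the 3' end with the Lexogen 3' FWD kit, per the labels' protocols, in 12 libraries of CD11c bead-enriched lymph node cells, 6 wildtype and 6 APOE-KO. The deposited table holds whole-number read counts per gene for 24499 gene symbols, not normalised. The authors' tools, per the submitters' processing notes, were STAR 2.7.8a, featureCounts 1.5.1, R 4.1.0 and DESeq2 1.4, with genome build mm10. Which gene annotation was used, whether counting was strand-specific, how reads with several matches were treated, whether molecular identifiers were used and whether reads were filtered are not given in the sources used here. Without those, counts of near-identical genes and of genes that overlap another are uncertain. Of the 102 genes named by the rule, 38 overlap a gene annotated on the other strand and 15 one on the same strand. A 3' library gives reads near the end of a transcript, so counts do not grow with gene length. Intervals and detection floors cover counting error only.

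Library columns were matched to samples by the short descriptions in the labels, and the genotype label set the groups. No column was left unused. Of the 24499 symbols, 7573 had no count in any library. Positions come from GENCODE vM21, an annotation of GRCm38, the assembly that mm10 also names. 23636 symbols matched it directly, 440 through a synonym, and 423 did not match. Library totals ran from 2381477 to 4898360 counts. At that depth, 3 counts in 1 library stand for 0.525 to 1.59 CPM, and the interval of a share of the whole library is narrow, as for Rn45s. Between-library variation, not depth, set the precision for well-covered genes (biological coefficient of variation 30.1%, from the common dispersion).

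Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept with filterByExpr (minimum count 10 in about 6 libraries at the median depth, total of at least 15), which left 10714. Libraries were scaled with TMM factors, and CPM values use the scaled library sizes. The test was glmQLFit and glmQLFTest on genotype alone, all 12 libraries, with Benjamini-Hochberg adjustment over the 10714 genes and a threshold of 0.05. Log2 fold changes are APOE-KO over wildtype as fitted, folds are their antilogs, and the SE is the size of the log2 fold change divided by the square root of the F statistic. Log2 CPM for principal components and list means used a prior count of 2. Same-numbered libraries gave no sign of pairing, and the labels do not say that the numbers pair them. The main test therefore used no replicate term. No 2 libraries of a group agreed within sampling noise, so none was counted as a duplicate.

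Gene lists, 43 in all, the genes to be named, the tests and most alternatives were fixed before the data were examined. The lists cover sterol and fatty acid metabolism, interferon and antigen presentation, dendritic cell function, stress, and markers of the cell types that a digested node on CD11c beads can hold. The 40 lists with at least 5 tested members were tested with camera (preset correlation between genes 0.01), with camera under an estimated correlation, and with fry. Apoe is in no list. The named genes are Apoe, the 12 largest rises and 12 largest falls among passing genes with a mean of at least 5 CPM, the 4 members with the smallest p of each list that passed, the 2 with the smallest p of 9 lists about sterols, interferon, presentation and maturation, and Itgax. Predicted genes, Gm and Rik names and ribosomal or histone pseudogenes were not named. Passing list members outside the rule are also named, chosen after their values were seen: Nr1h3, Arl4c, Ctsz, Cacnb3, Eno2, Oasl2, Cox6a2, Bcl11a, Sirpa, Clec10a, Tnfrsf4, Cxcl13, Clu and Aldoa. Some genes that the rule names are not reported here.

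The test and the list test were run on simulated counts with the means, depths and dispersions of these libraries, 200 changed genes and 5 simulations of 10714 genes. Of genes changed 1.5-fold, 2-fold and 3-fold, 19.4%, 56.7% and 80.3% were recovered, and 6.19% of calls were false. All 5 shifted lists of 20 genes (1.5-fold) and 0 of 195 unchanged lists passed, but simulated genes were independent of each other, unlike real ones. Single values were compared by exact permutation tests over the 924 assignments of 6 of 12 libraries. Alternatives were other size factors, other filters, DESeq2 1.42.0, limma-voom, robust dispersion, a replicate block, a surrogate variable (sva 3.50.0), covariates for B and T cell markers, for Rn45s and for epithelial markers, and fits leaving out each library in turn.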

Results

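The data set compares cells enriched for CD11c from tumour-draining lymph nodes of wildtype mice and of mice lacking apolipoprotein E (APOE-KO). CD11c, the integrin encoded by Itgax, is carried by dendritic cells and by some macrophages. Mice received E0771-cOC cells (E0771 is a mouse mammary carcinoma line), and the nodes were taken on day 9 after injection, minced, digested with collagenase and DNase, and passed over CD11c beads. RNA was sequenced from the 3' end. There were 12 libraries, 6 wildtype and 6 APOE-KO, holding between 2381477 and 4898360 counts each. The log2 totals did not differ detectably between the genotypes (two-sided exact permutation p = 0.455). Nothing in the labels says that the libraries come from separate animals, so p-values measure the spread between these samples, which may be technical.

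The 45S ribosomal RNA gene Rn45s took very different shares of the counts, from 2.712% in wildtype library 3 (95% exact binomial interval 2.698 to 2.726) to 32.2% in wildtype library 1 (32.1 to 32.3). By genotype its share was 14.7% ± 10.5 in wildtype and 15.7% ± 4.69 in APOE-KO (SD, n = 6 each; two-sided exact permutation p = 0.844). Some libraries stood apart in principal components of the 500 most variable genes: APOE-KO library 5 on the component holding 25.4% of the variance, wildtype library 1 on that holding 18.9%, and wildtype library 3 on that holding 14.6%. Xist was present in every library with 6517 to 12287 reads. Of the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y, no library held more than 1 read, so the genotypes were not split by sex.

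Apoe itself, the lipid-carrier gene targeted in the knockout, was read first because it checks the labels. It lies on chromosome 7 from 19696109 to 19699188 on the minus strand (GRCm38, a protein-coding gene). Its level was 481 ± 45.7 CPM in wildtype and 5.81 ± 2.95 CPM in APOE-KO (SD, n = 6 each), 86.1-fold lower, with a log2 fold change of -6.43 ± 0.23 (SE) and an adjusted p of 5.25e-16 in edgeR's quasi-likelihood test. Every wildtype library held between 838 and 2919 Apoe reads and every APOE-KO library between 13 and 30. The two-sided exact permutation p was 0.00216, the smallest that the 924 assignments of 6 of 12 libraries can give. How the allele was made, and where its reads would end, is not given in the sources used here.

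**Figure D1:**
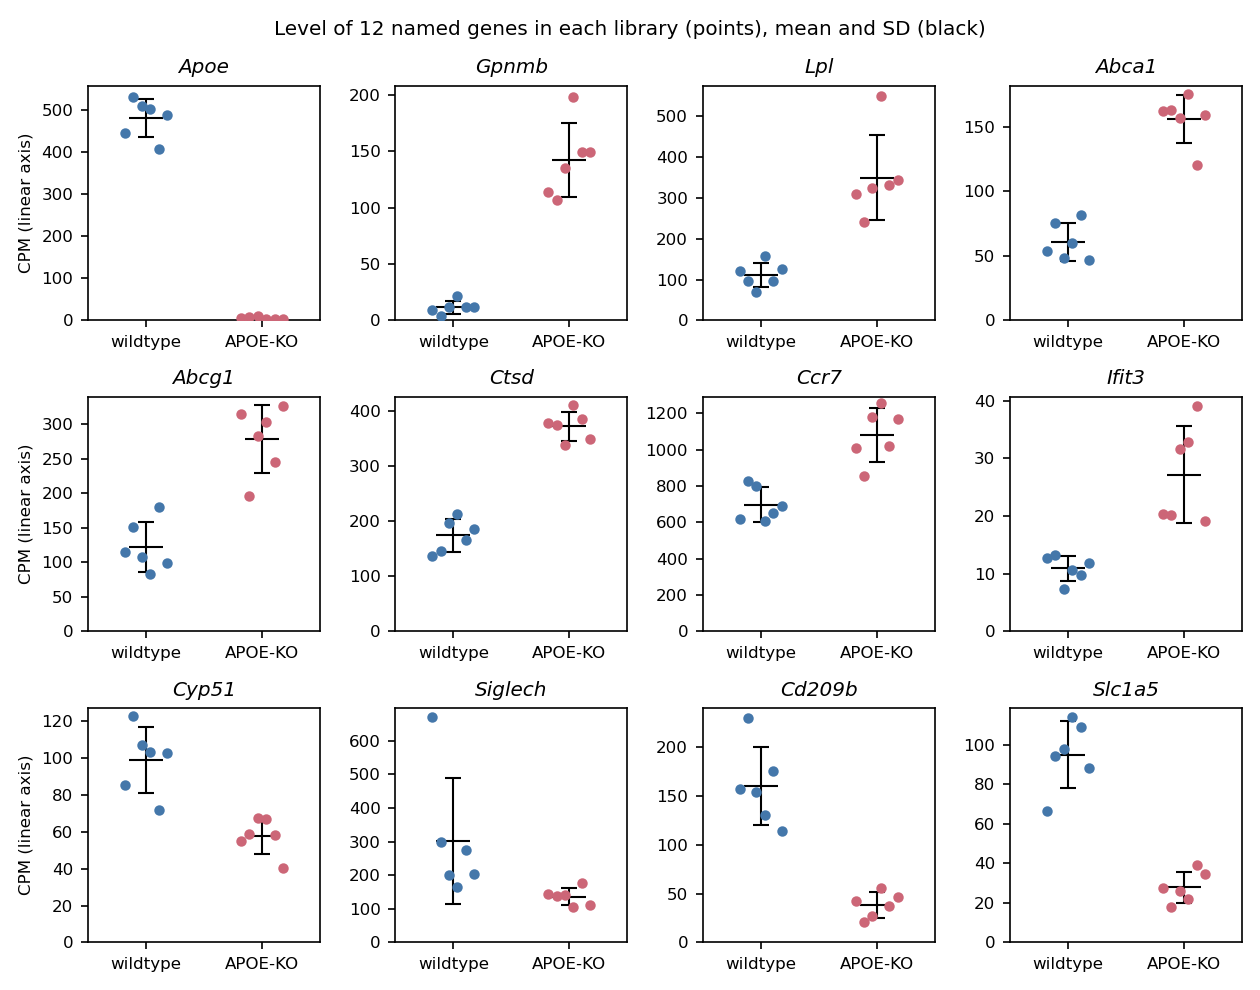
CPM (linear vertical axis from 0) of 12 named genes in each of the 6 wildtype (blue) and 6 APOE-KO (red) libraries; black lines give mean and SD. The groups overlap in the Siglech panel, where wildtype library 1 stands at 669 CPM, and in no other.

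The series' single comparison asks how these CD11c-enriched cells differ between APOE-KO and wildtype mice. Of 10714 genes tested, 160 passed an adjusted p of 0.05, 116 higher and 44 lower in APOE-KO. The gene that rose with the smallest p was Gpnmb, a glycoprotein of lysosomes and phagocytes, at 11.8 ± 5.70 CPM in wildtype and 142 ± 32.7 CPM in APOE-KO (SD, n = 6 each; 11.8-fold, log2 fold change 3.56 ± 0.25 SE, adjusted p = 1.93e-09). Cd5l, a secreted scavenger protein of macrophages, rose 5.07-fold (adjusted p = 4.23e-06), and Lpl, lipoprotein lipase, rose 3.15-fold from 111 ± 30.5 to 350 ± 105 CPM (adjusted p = 9.24e-06). Atp6v0d2, a subunit of the vacuolar proton pump, went from 13 reads over the 6 wildtype libraries to 271 over the 6 APOE-KO libraries, with a log2 fold change of 4.35, or 6.38 without wildtype library 4. Among falling genes, the C-type lectin Cd209b dropped 4.17-fold, from 160 ± 40.1 to 38.1 ± 12.9 CPM (adjusted p = 1.89e-06), and the glutamine transporter Slc1a5 dropped 3.40-fold, from 94.95 ± 16.9 to 27.9 ± 8.00 CPM (adjusted p = 3.82e-06). For each of these genes every APOE-KO library lay beyond every wildtype library.

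Among genes averaging at least 5 CPM, the other largest rises were in Apoc1, an apolipoprotein, Mmp19 and Mmp12, matrix metalloproteinases, Aldh1a2, a retinaldehyde dehydrogenase, F10, coagulation factor X, Clec4e, a C-type lectin receptor, and Lilr4b, at 2.87-fold to 4.89-fold. The other largest falls were in Cbr2, a carbonyl reductase (25.7-fold, 264 reads over wildtype against 10 over APOE-KO), Bpifb2, Bpifb3, Gpx3, a secreted glutathione peroxidase, Uaca, Folr2, a folate receptor of macrophages, Adgrg1, Dab2 and Sdpr, at 3.01-fold to 8.33-fold. Of the genes in this paragraph, Aldh1a2 and Folr2 alone had groups that overlapped. Of the 160 genes, 113 had groups that did not overlap, as had 190 of all tested genes, where chance alone gives 0.216% of genes. A log2 fold change of at least 1 either way was reached by 67 genes, 39 higher and 28 lower. Leaving out APOE-KO library 3 reduced the count to 99 genes (72 higher, 27 lower), and the lower genes numbered 27 without wildtype library 5 and 29 without APOE-KO library 6. Taking the mean of the epithelial marker list as a covariate, chosen after the data were seen, left 33 genes and ended the calls of 39 named genes. The median size of their log2 fold change was 1.14 before and 1.10 after, and their median SE 0.22 and 0.34. Of the fits without 1 library, Folr2 passed only without wildtype library 3 or 6 or APOE-KO library 5 or 6 (adjusted p up to 0.104), and Adgrg1 only without wildtype library 1 or 2 or APOE-KO library 2 or 4 (up to 0.111). Uaca passed only without wildtype library 2, 3 or 4 or APOE-KO library 4, 5 or 6 (up to 0.0746), and Bpifb2 did not pass without wildtype library 5 (0.0501). The log2 fold change of Cbr2 was -4.68, or -6.41 without APOE-KO library 5, and that of Bpifb2 was -3.06, or -4.08 without APOE-KO library 3.

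Genes activated by the sterol-sensing liver X receptors (LXR) were higher in APOE-KO as a group. Of 15 tested members 8 rose, or 10 adjusted over the list alone, and none fell. The sterol efflux transporters Abca1 and Abcg1 rose 2.56-fold (60.9 ± 14.7 to 156 ± 18.7 CPM, adjusted p = 1.04e-05) and 2.27-fold (123 ± 36.4 to 278 ± 49.2 CPM, adjusted p = 0.000247). The desaturases Scd2 and Scd1 rose 2.08-fold and 1.61-fold, and Nr1h3, which encodes LXR alpha, rose 2.01-fold. Lpl, Apoc1 and Arl4c rose as well, and in none of these members did the groups overlap. The list passed camera's test with an adjusted p of 2.82e-23, and with an adjusted p of 2.58e-05 when the correlation between genes was estimated. With the epithelial mean as a covariate, the list still passed, but of its members named by the rule Scd1 and Apoc1 did not.

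Cholesterol synthesis moved the opposite way. Of 17 tested members 2 fell, 4 adjusted over the list alone, and 15 had a negative log2 fold change. The members that fell were Cyp51, lanosterol demethylase, at 1.71-fold (98.8 ± 17.8 to 57.8 ± 9.84 CPM, adjusted p = 0.00951), and Sqle, squalene epoxidase, at 2.72-fold (adjusted p = 0.0482). Groups did not overlap for Cyp51 and Sqle. As a whole the list passed with adjusted p = 1.64e-05 (adjusted p = 0.0161 with an estimated correlation). The call of Sqle rested on 266 and 100 reads and held, among fits without 1 library, only without wildtype library 1 or 2 (adjusted p up to 0.156). With the epithelial mean as a covariate neither gene passed.

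The list of sterol sensing and lipoprotein receptors did not pass (adjusted p = 0.0634, and 0 of 15 members past the threshold). Stard4, a sterol carrier, had 22.1 ± 8.26 and 9.80 ± 1.54 CPM (adjusted p = 0.0651) and passed without wildtype library 3 (0.00185). Fatty acid synthesis and desaturation passed upward with adjusted p = 0.0284, and adjusted p = 0.238 with an estimated correlation. Its 2 members that rose, Scd1 and Scd2, are shared with the LXR list, 11 of its 13 members did not pass, and Fads1 had 24.6 ± 6.58 and 14.4 ± 6.01 CPM (adjusted p = 0.199). That list's call also ended without wildtype library 5, APOE-KO library 2, 5 or 6 (adjusted p up to 0.0958). Fatty acid oxidation did not pass (adjusted p = 0.0726).

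Genes of lipid uptake and storage rose in 4 of 17 members, or 5 adjusted over the list alone. Besides Gpnmb, these were Lgals3, galectin-3, at 1.94-fold (240 ± 36.1 to 465 ± 65.3 CPM, adjusted p = 0.000132), Fabp5, a fatty acid binding protein, at 2.31-fold (adjusted p = 0.000247), and Mgll, monoglyceride lipase, at 1.75-fold (adjusted p = 0.0458; of the fits without 1 library it passed only without wildtype library 3 or 4 or APOE-KO library 2, adjusted p up to 0.145). Lipid uptake and storage passed with adjusted p = 1.15e-08, and with adjusted p = 0.0161 under an estimated correlation. However, 13 of its members did not pass. Among them were Plin2 and Cd36, chosen after their values were seen (each 1.21-fold higher, adjusted p = 0.566 and 0.741). Lysosomal and phagocytic genes rose in 5 of 21 members, the proteases Ctsd (2.13-fold, 174 ± 29.7 to 372 ± 26.3 CPM, adjusted p = 1.04e-05), Ctsb (1.52-fold) and Ctsz (1.52-fold), the membrane protein Lamp1 (1.53-fold, adjusted p = 0.00245) and Atp6v0d2. Adjusted over the list alone, 8 rose and 2 fell, and groups overlapped for Mgll and Ctsz. That list passed with adjusted p = 1.15e-08, and with adjusted p = 0.00993 under an estimated correlation.

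In the oxidative stress list 2 of 19 members rose, 5 adjusted over the list alone. They were the cystine transporter Slc7a11, at 2.01-fold (36.6 ± 7.55 to 73.7 ± 21.0 CPM, adjusted p = 0.00565), and Ftl1, the ferritin light chain, at 1.69-fold (adjusted p = 0.00194), whose reads can be shared with processed copies. Groups overlapped for Slc7a11 and not for Ftl1. This list passed with adjusted p = 1.09e-06, and with adjusted p = 0.00435 under an estimated correlation. The calls of Mgll, Ctsb, Lamp1 and Ftl1 ended with the epithelial mean as a covariate.

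**Figure D2:**
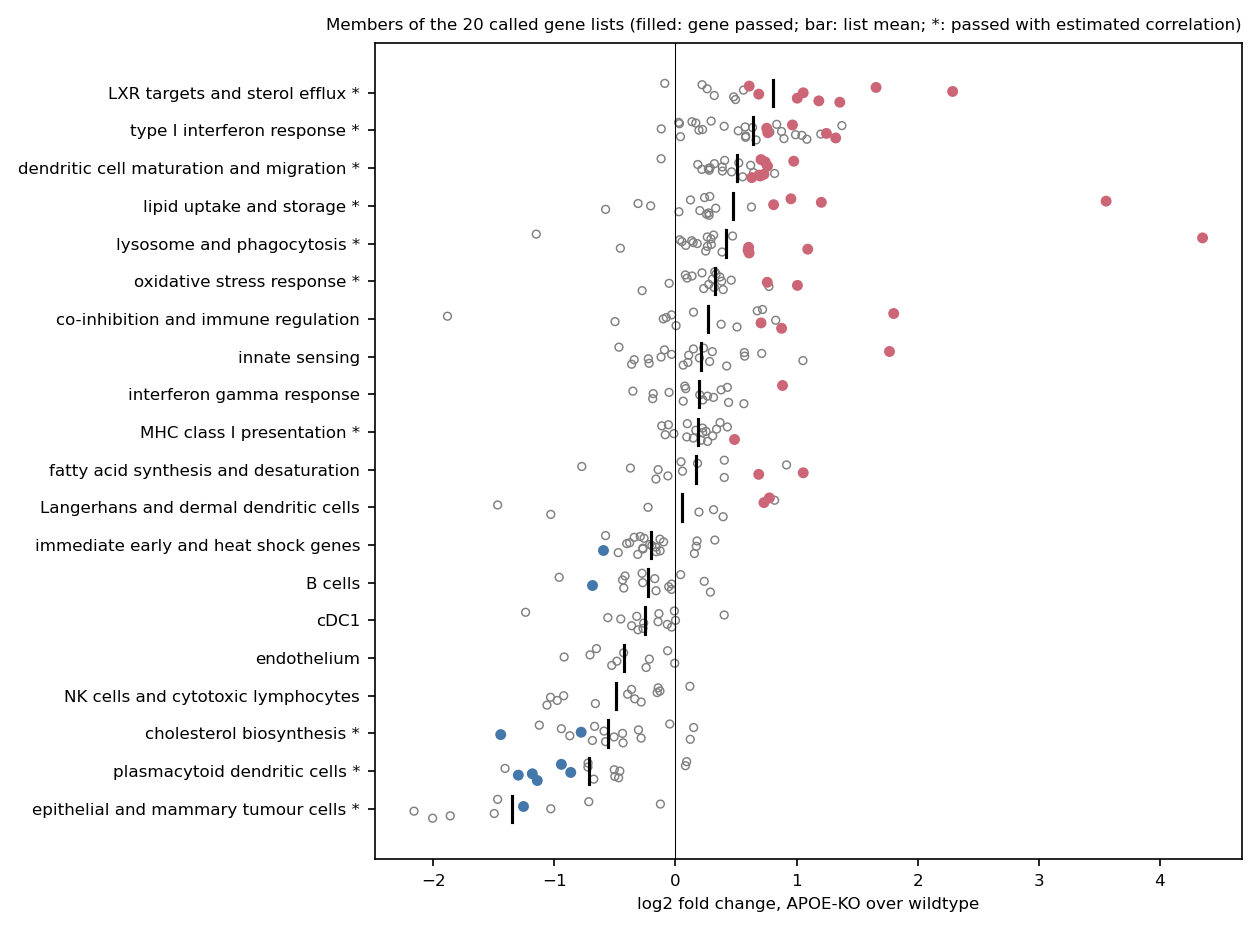
Log2 fold change (APOE-KO over wildtype, horizontal axis) of every tested member of the 20 lists that passed camera's test; each circle is a gene, filled red or blue where it passed as higher or lower, black bars are list means, and stars mark the 10 lists that also passed with an estimated correlation. The LXR list has the highest mean and the epithelial list the lowest.

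Dendritic cell maturation genes were higher in APOE-KO, while the gene of the bead target did not change detectably. Of 24 tested maturation and migration genes 8 rose, 18 adjusted over the list alone, and 23 had a positive log2 fold change. Ccr7, the chemokine receptor that brings dendritic cells into nodes, rose 1.55-fold (698 ± 94.1 to 1082 ± 147 CPM, adjusted p = 0.00444). Anxa3 rose 1.67-fold (adjusted p = 0.00254), Tmem123 1.69-fold (1791 ± 421 to 3034 ± 640 CPM), Marcksl1 1.61-fold, and Cacnb3, Ccl22, Eno2 and Socs2 also rose. Groups overlapped for Tmem123, Socs2 and Ccl22. Maturation genes passed as a list with adjusted p = 2.52e-20, and with adjusted p = 0.0187 under an estimated correlation. Itgax stood at 278 ± 54.0 and 298 ± 36.9 CPM (log2 fold change 0.10 ± 0.14 SE, adjusted p = 0.841).

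Markers of conventional dendritic cells did not pass as a list (adjusted p = 0.99). Their median log2 fold change was 0.052 and their mean -0.006, and 1 of 17 members, Bcl11a, fell. MHC class II presentation did not pass (adjusted p = 0.694, median -0.068, mean 0.003); its 1 member that rose was Lgmn, a lysosomal protease, at 2.20-fold (adjusted p = 0.00236). Co-stimulation did not pass either (adjusted p = 0.0726), with Icam1 and Cd40 at 1.35-fold and 1.32-fold higher levels and adjusted p of 0.163 and 0.191. In the co-inhibition list 3 of 15 members rose, Aldh1a2 (3.49-fold), Cd274, which encodes PD-L1 (1.84-fold, adjusted p = 0.0213), and Socs2, a cytokine signalling suppressor (1.63-fold, adjusted p = 0.0133). Adjusted over the list alone, 6 rose and 1 fell. It passed with adjusted p = 0.0071 but not with an estimated correlation (adjusted p = 0.0694), and groups overlapped for all 3 genes. Cd274 did not pass without wildtype library 5 or 6 or APOE-KO library 4 or 6 (adjusted p up to 0.0788), and Socs2 did not pass with a replicate block (0.0741). Il10 held 155 reads over wildtype and 40 over APOE-KO, with an adjusted p of 0.134.

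Type I interferon response genes had a positive log2 fold change in 29 of 30 tested members, of which 5 rose, or 11 adjusted over the list alone. Ifit3 rose 2.50-fold (10.9 ± 2.19 to 27.2 ± 8.42 CPM, adjusted p = 0.00522), Irf7, the regulator of interferon genes, 1.70-fold (adjusted p = 0.00989), and Oasl2, Rtp4 and Ifi27l2a also rose, with groups that did not overlap for Ifit3 and Rtp4. Their list passed with adjusted p = 1.99e-13 (adjusted p = 0.0161 with an estimated correlation). Rtp4 did not pass without wildtype library 5 or APOE-KO library 3 or 6 (adjusted p up to 0.0882), nor Ifi27l2a without wildtype library 4 or APOE-KO library 1, 3 or 6 (up to 0.0796), and Ifit3 has a near-identical copy that can share its reads. MHC class I presentation passed with adjusted p = 0.00145 (adjusted p = 0.0187 with an estimated correlation), with 14 of 18 members positive. The 1 member that rose, also adjusted over the list alone, was B2m, the class I light chain, at 1.4-fold (3185 ± 320 to 4460 ± 599 CPM, adjusted p = 0.0159). The calls of Ifit3, Irf7, Rtp4, Ifi27l2a, B2m, Ccr7, Anxa3, Marcksl1, Ccl22 and Cd274 ended with the epithelial mean as a covariate, while their lists still passed.

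Weaker lists were the interferon gamma response (1 of 16 rose, Cd274; adjusted p = 0.0363, and adjusted p = 0.177 with an estimated correlation) and innate sensing (1 of 22 rose, Clec4e; adjusted p = 0.0314, and adjusted p = 0.0999 with an estimated correlation). Immediate early and heat shock genes, which respond to tissue handling among other stimuli, passed downward with adjusted p = 0.0011, and adjusted p = 0.116 with an estimated correlation. Egr1 was the 1 member of 22 that fell, 1.51-fold (670 ± 91.4 to 442 ± 52.0 CPM, adjusted p = 0.00689), and Jun had 437 ± 78.8 and 315 ± 30.5 CPM (adjusted p = 0.0651). The interferon gamma call ended without wildtype library 3, 4 or 6 or APOE-KO library 4 or 5 (adjusted p up to 0.0828), and the innate sensing call without wildtype library 1 or 2 or APOE-KO library 1 (up to 0.068). With the epithelial mean as a covariate, innate sensing, Clec4e and Egr1 did not pass.

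Among cell type markers, those of plasmacytoid dendritic cells were lower in APOE-KO. Of 15 tested members 5 fell, 12 adjusted over the list alone: Siglech, a lectin of these cells (2.20-fold, 302 ± 187 to 136 ± 25.2 CPM, adjusted p = 0.0133), Klk1 (2.27-fold), Cd209d (1.92-fold), Runx2 (1.82-fold) and Cox6a2 (2.46-fold). Cd209d stands also in the list of cDC2 markers, and Klk1 and Cd209d belong to families of similar genes. Plasmacytoid markers passed with adjusted p = 3.3e-12, and with adjusted p = 0.037 under an estimated correlation. Wildtype library 1 held 669 CPM of Siglech, the other wildtype libraries 165 to 298 CPM, and groups overlapped for Siglech and Cox6a2. Without wildtype library 1 the log2 fold change of Siglech was -0.75 in place of -1.14, and its call ended under robust dispersion (adjusted p = 0.0865). The calls of Siglech, Klk1 and Runx2 ended with the epithelial mean as a covariate.

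Macrophage markers moved in both directions, and the list did not pass camera's directional test (adjusted p = 0.897, median log2 fold change 0.17, mean -0.113). Of 17 tested members Cd5l and the complement gene C1qb rose. Timd4, a receptor for phosphatidylserine, fell 2.14-fold, the scavenger receptor Marco 2.92-fold (243 ± 53.7 to 83.2 ± 16.4 CPM, adjusted p = 3.15e-06), the mannose receptor Mrc1 2.66-fold, and Folr2 4.57-fold. Groups overlapped for Mrc1 and Folr2 among these genes. Timd4, Marco, Mrc1 and C1qb lie outside the rule for naming genes and were chosen after their values were seen. Fry's test for change in either direction gave an adjusted p of 1.17e-09. A value under 0.05 in that test was not particular to macrophages. Other lists that did not pass camera's test had one too, such as conventional dendritic cells (0.00127), MHC class II presentation (0.00123) and inflammatory cytokines (1.34e-05). The cell cycle list did not (0.456).

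Further cell type lists passed with the preset correlation but not with an estimated one. These were endothelium (0 of 10 past the threshold; adjusted p = 0.00247, and adjusted p = 0.189 with an estimated correlation), NK cells (0 of 13; adjusted p = 0.018, and adjusted p = 0.36 with an estimated correlation), cDC1 (0 of 15; adjusted p = 0.0222, and adjusted p = 0.177 with an estimated correlation) and B cells (1 of 15, Fcer2a; adjusted p = 0.0284, and adjusted p = 0.124 with an estimated correlation), all downward. The cDC1 marker Xcr1 had 183 ± 26.3 and 148 ± 25.3 CPM, with an adjusted p of 0.362. Langerhans and dermal dendritic cell markers passed upward with adjusted p = 0.045 (adjusted p = 0.177 with an estimated correlation). Cd63 and Ccl22 rose 1.71-fold and 1.66-fold there. The endothelial call ended without wildtype library 1 or 2 (adjusted p up to 0.0729), the NK cell call without wildtype library 4 (0.154), the cDC1 call without wildtype library 3 or 6 (up to 0.0697) and the B cell call without wildtype library 4 or APOE-KO library 3 (up to 0.113). The Langerhans call ended without wildtype library 2, 4 or 5 or APOE-KO library 4, 5 or 6 (up to 0.0996), and Fcer2a passed only without wildtype library 3, 4 or 6 or APOE-KO library 5 (up to 0.143).

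Lists that did not pass were cDC2 (adjusted p = 0.147; Sirpa rose, Clec10a and Cd209d fell), T cells (0.21), regulatory and activated T cells (0.135; Tnfrsf4 rose), monocytes (0.238), neutrophils (0.457), germinal centre B cells (0.621), plasma cells (0.621) and fibroblastic stroma (0.687; Cxcl13 and Clu rose). Nor did inflammatory cytokines (0.227), cell cycle (0.551), glycolysis and hypoxia (0.147; Aldoa rose), oxidative phosphorylation (0.0652), the unfolded protein response (0.551) or cytosolic ribosomal proteins (0.188). Values in brackets are adjusted p from camera. Lists of erythroid cells, platelets and mast cells had 0, 3 and 1 tested members and were not tested. In all, 20 of 40 lists passed, 12 upward and 8 downward, and 10 passed with an estimated correlation.

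Epithelial and mammary tumour markers were lower in APOE-KO, unevenly between libraries. Of 9 tested members 1 fell, E-cadherin (Cdh1, 2.39-fold, 38.96 ± 12.1 to 16.4 ± 7.71 CPM, adjusted p = 0.0172), and 7 fell adjusted over the list alone. Groups overlapped for Cdh1. Epithelial markers passed with adjusted p = 2.29e-08, and with adjusted p = 0.037 under an estimated correlation. Its mean log2 CPM was 3.48 ± 0.23 in wildtype and 1.80 ± 1.04 in APOE-KO (SD, n = 6 each). The summed level of the keratins Krt7, Krt8, Krt18 and Krt19 lay between 29.2 and 55.3 CPM in wildtype libraries. In APOE-KO libraries 1 to 6 it was 12.4, 0, 5.34, 57.0, 1.99 and 0.212 CPM. The 0 in APOE-KO library 2 allows up to 0.989 CPM (3 counts, counting error only). Krt18, with 21.7 ± 7.69 and 5.95 ± 10.2 CPM, did not pass (adjusted p = 0.202). It passed without APOE-KO library 4 (0.0018), with a replicate block (0.04), with no filter on low counts and in limma-voom.

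Genes near Apoe on chromosome 7 were called more often than genes elsewhere. Within 10 Mb of Apoe, 9 of 153 tested genes passed (5.88%), Apoe itself left out, against 149 of 10489 elsewhere (1.42%), an odds ratio of 4.34 (95% interval 1.91 to 8.69, two-sided Fisher's exact test, p = 0.00045). Higher genes included Apoc1, Zfp296, Pvr, Pglyrp1, Pld3 and Gmfg, and Slc1a5 and Ube2m were lower. Apoc1 (19689481 to 19692660) lies 0.00658 Mb from Apoe, and Slc1a5 (16781340 to 16798274) lies 2.91 Mb away, midpoint to midpoint. Zfp296 overlaps Gemin7 on the other strand, as Gmfg overlaps Samd4b, so their reads are uncertain where counting ignored strand. Zfp296, Pvr, Pglyrp1, Pld3, Gmfg and Ube2m were named after their values were seen.

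**Figure D3:**
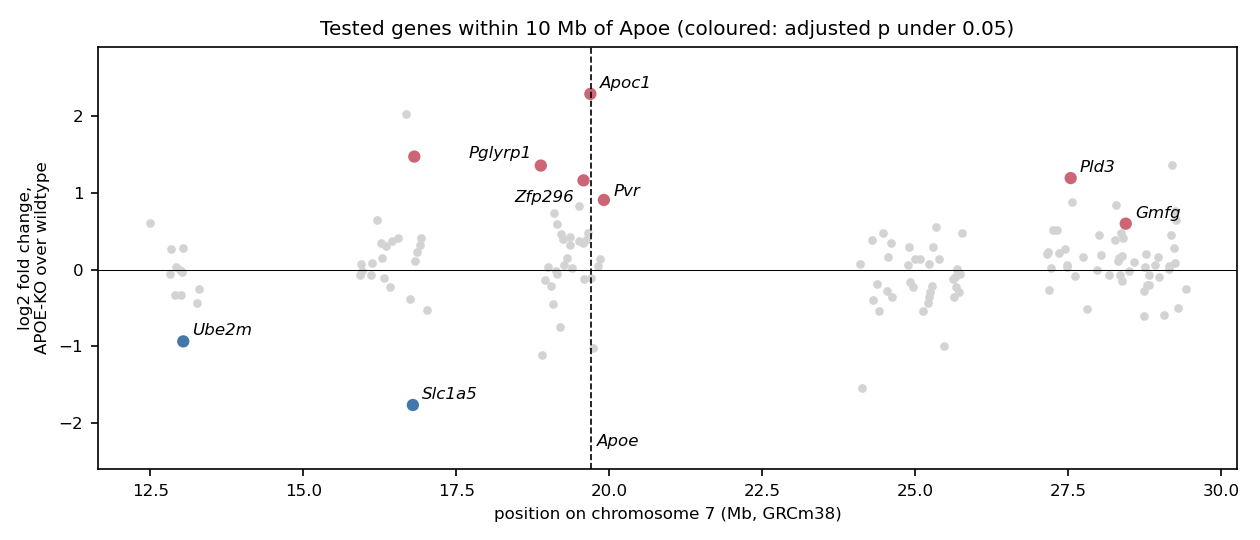
Log2 fold change (APOE-KO over wildtype) of the 153 tested genes within 10 Mb of Apoe by their midpoint on chromosome 7 (Mb, GRCm38); coloured points passed an adjusted p of 0.05 and the dashed line marks Apoe. The 7 red points were higher and the 2 blue points lower in APOE-KO.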

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

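Of the tests in this part, the comparison of the keratin sum between genotypes was chosen only after the result was seen. In each genotype every named gene, every passing list, the library totals and the Rn45s shares were searched for a library lying far from the other 5. Of 248 such sets of 6 libraries, 24 (9.68%) held one, where chance gives about 1 in 20.

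Wildtype library 1, the library with most Rn45s, stood high for Siglech (669 CPM, the others 165 to 298), Bpifb3 (19.1 CPM, the others 7.65 to 11.4) and Cd209d (193 CPM, the others 115 to 139). Wildtype library 3, with least Rn45s, stood low for Stard4 (5.60 CPM, the others 23.4 to 28.2) and for the mean log2 CPM of the type I interferon list (4.18, the others 4.60 to 4.84), and high for Cd22 (81.2 CPM, the others 46.7 to 59.4). Wildtype library 2 stood high for Socs2 (199.9 CPM) and for the mean of the dendritic cell maturation list (7.70). Wildtype library 4 stood high for Atp6v0d2 (2.50 CPM, the others 0 to 0.556) and for the mean of the lysosome list (7.07). Wildtype library 5 had the lowest mean of the immediate early list (7.52), and wildtype library 6 the lowest mean of the epithelial list (3.02). Without wildtype library 3, Stard4 passed (adjusted p = 0.00185).

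APOE-KO library 5 stood apart for Abca1 (120 CPM, the others 157 to 175), Mmp19 (18.4 CPM), Cbr2 (1.99 CPM), Fads1 (25.6 CPM, the others 8.47 to 14.5) and Tapbp (636 CPM, the others 450 to 506). Without it, Fads1 passed as lower in APOE-KO (adjusted p = 0.0449). APOE-KO library 6 stood high for Gzma, a granzyme (109 CPM, the others 15.2 to 25.4), Klrd1 (99.0 CPM), Folr2 (3.81 CPM) and the mean of the NK cell list (4.44, the others 2.86 to 3.44). Leaving it out, Gzma passed as lower (adjusted p = 0.0185). APOE-KO library 3 had 6.76 CPM of Bpifb2, the others at most 2.29 CPM. APOE-KO library 4 held most Lpl (549.8 CPM, the others 240 to 344) and most Krt18 (26.3 CPM, the others 0 to 5.27).

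The Krt18 value belongs to a wider pattern: keratins were near wildtype level in APOE-KO library 4 and low in the other 5 APOE-KO libraries. The keratin sum differed between genotypes (two-sided exact permutation p = 0.0195), as it would if the node's epithelial or tumour cells differed by genotype, but also if mammary tissue was kept with some nodes at dissection, and the design cannot separate these. A test of the second written beforehand, whether 22 other epithelial genes rose with the keratins within the 6 APOE-KO libraries, gave Spearman's rho = 0.429 (one-sided exact p = 0.21, BH-adjusted two-sided p = 0.714 over 4 relations) and Pearson's r = 0.722 (two-sided exact p = 0.0528), or r = -0.107 without the 2 farthest libraries. Their summed level was 77.6 to 113 CPM in APOE-KO and 86.0 to 113 CPM in wildtype. APOE-KO library 2 had 0 keratin reads and 104 CPM of these genes, so most of the sum arose without the keratins. With that measure and 6 libraries the test could not decide. Both explanations stay open, and Prlr, the prolactin receptor, noticed after its values were seen, was at 110 CPM in APOE-KO library 4 and 0 in libraries 5 and 6.

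Chance as the source of the main counts was examined with 100 of the 462 splits of the 12 libraries, the real one included. The real split called 160 genes and the highest other 3, so 1 of 100 splits gave as many, the smallest share possible. A chance division of these libraries can be excluded for that count. For the preset lists the real split called 20 and the highest other 17, so 1 of 100 splits gave as many. That margin is narrow and not all of the 462 splits were drawn, so chance is less firmly excluded for the list count. Neither share bears on a batch or handling difference that ran with genotype. Nor does either bear on chance differences between animals, if libraries of a genotype shared animals. The 17 came from a split in which 5 of the 6 libraries of each group kept their genotype together. The 45 splits that kept 3 together called up to 8 lists and 0 genes. Lists can thus pass at the preset correlation without a genotype difference, so a list call resting on that setting alone is uncertain.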

How the results depend on the processing

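The tests with Rn45s left out, with Rn45s or epithelial covariates, without 3 libraries together, and with lists lacking members near Apoe were chosen after the data were seen. The Apoe call and the direction of every called list held in all settings run. Relative to 160 genes (116 higher, 44 lower), DESeq2's Wald test called 270 (185 higher, 85 lower), among them 147 of the 160, the other 13 having no adjusted p there; the fit with no filter called 233 (68 lower); 1 surrogate variable 239 (73 lower); the Rn45s covariate 265 (185 higher, 80 lower), including all 160. The epithelial covariate left 33 (25 higher, 8 lower), 31 shared; of 39 named genes whose calls ended, all 39 had a larger SE and 24 a larger fold. Under it Krt18 and Krt7, members of that list, reversed to 0.12 and 0.13 (log2), by its construction. For the other shifts the cause was not tested. Without 1 library the count ran from 99 (APOE-KO library 3) to 230 (wildtype library 3), higher genes from 72 to 166 and lower genes from 27 to 64. Without wildtype libraries 1 and 3 and APOE-KO library 5, 186 passed, 128 of them shared.

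Same-numbered libraries of the 2 genotypes showed no shared deviation (correlations -0.077 to 0.018), and no library correlated best with its own number. That gives no sign that the numbers pair libraries, but it cannot exclude pairing. A replicate block gave 100 genes (70 higher, 30 lower), 95 shared. The block ended the calls of Uaca, Folr2, Adgrg1, Sqle, Rtp4, B2m and Socs2, robust dispersion that of Siglech, and leaving out 3 libraries those of Mmp19, Uaca, Sqle, Mgll, Rtp4, B2m, Fcer2a and Cdh1. Of the 20 lists, 10 passed with an estimated correlation, and between 15 and 20 of them under the other settings run on lists. Of 60 named genes past the threshold, 50 passed in every fit without 1 library. Odds ratios for genes near Apoe were 7.09, 2.55 and 3.33 with windows of 5 and 20 Mb and at unadjusted p under 0.01. Depth limits the low genes: Atp6v0d2, Cbr2 and Krt7 rest on 13, 10 and 29 reads in their lower group.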

Other observations

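Genes in this paragraph and the next, except Cd209b and Cd209d, lie outside the naming rule and were chosen after their values were seen. Complement gene C3 rose 2.32-fold in APOE-KO (148 ± 26.5 to 343 ± 62.7 CPM, SD, n = 6 each, adjusted p = 1.41e-05, edgeR), with every APOE-KO library (278 to 453 CPM) above every wildtype library (114 to 178 CPM). Properdin (Cfp) rose 1.54-fold and factor B (Cfb) 1.46-fold, while C1qa and C1qc, which with C1qb encode the chains of C1q, had adjusted p of 0.66 and 0.676. The chemokine genes Cxcl13, Ccl6 and Cxcl16 rose 2.30-fold, 1.74-fold and 1.72-fold (adjusted p = 0.00219, 0.00254 and 0.000473). Ctsk, a collagen-degrading cathepsin, had 7 reads over the 6 wildtype libraries and 185 over the 6 APOE-KO libraries (adjusted p = 0.00223). Pla2g7, which encodes lipoprotein-associated phospholipase A2, rose 2.13-fold (adjusted p = 0.00254).

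The falling genes included a further Cd209 family member, Cd209f, with 167 reads over wildtype and 7 over APOE-KO (adjusted p = 0.000934), beside Cd209b and Cd209d. The lectin gene Clec10a fell 1.84-fold (159 ± 33.1 to 86.6 ± 17.8 CPM, adjusted p = 0.00345) and the transcription factor gene Maf 1.85-fold (adjusted p = 0.00565). Pgr, the progesterone receptor gene, had 132 reads over wildtype and 17 over APOE-KO (adjusted p = 0.0228). MHC class II genes H2-Aa, H2-Ab1 and Cd74 had 6349 ± 1139, 3071 ± 356 and 2403 ± 347 CPM in wildtype, with adjusted p of 0.875, 0.984 and 0.989.

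Of the tests that follow, all 4 on genes near Apoe and the one on a share of macrophages were chosen after their results, or results close to them, were seen; the count itself was planned. Genes near Apoe were called more often than elsewhere. Loss of Apoe acting on genes whatever their position would give no such excess if called genes were spread evenly. The odds ratio of 4.34 (95% interval 1.91 to 8.69) is that excess itself and treats neighbouring genes as independent. Windows elsewhere held up to 11.8% called genes, so the ratio cannot decide against this cause. Reads of another strain's alleles mapping less well would lower counts, and 77.8% of the 9 called genes were higher; for the 2 lower genes, Slc1a5 and Ube2m, it stays open. Sequence of another strain kept around the targeted allele is a candidate explanation. The called share around Apoe stood at the 99.5th percentile of equal windows around genes more than 20 Mb away (98.9th around all genes). Those 8818 windows were each centred on a tested gene and overlap their neighbours, so they are not independent regions. The highest share elsewhere was 11.8% against 5.88%. That percentile measures the same excess again, and any local cause would give it. Effects of the targeting construct on its neighbours, such as Apoc1, were not tested.

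Macrophage markers were called in both directions. A different share of macrophages in the APOE-KO preparations, acting alone, would move them together. The SD of their log2 differences was 1.08 against a median of 0.377 over assignments (exact permutation p = 0.00216, the smallest that 924 can give). That test restates the calls in both directions, and it argues only against a different share as the sole cause. Mammary tissue kept with the wildtype nodes was tested with the epithelial mean as a covariate: the median size of the log2 fold change of the 6 called genes was 1.48 before and 1.54 after. The folds did not shrink, but the epithelial mean itself ran with genotype (3.48 ± 0.23 log2 CPM in wildtype, 1.80 ± 1.04 in APOE-KO, SD). The fit therefore cannot exclude mammary tissue. Of the 6 called genes, Marco and Cd5l passed with the covariate. The SE grew in each of the other 4, by more than the fold except in C1qb (before and after, Folr2 -2.19 ± 0.53 and -2.66 ± 0.95, Mrc1 -1.41 ± 0.26 and -1.56 ± 0.43, Timd4 -1.10 ± 0.19 and -1.09 ± 0.32, C1qb 0.60 ± 0.15 and 0.91 ± 0.21). With the covariate 566 genes had an unadjusted p under 0.05, against 1294 without it, so the Benjamini-Hochberg adjustment was stricter. C1qb lost its call under that adjustment (adjusted p = 0.0648), although its fold grew by more than its SE. Hypotheses left open are a change in which macrophages the nodes hold and a change of expression within them. A different macrophage share together with either, and mammary tissue kept with the wildtype nodes, stay open too. Bulk libraries cannot separate these.

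Sterol synthesis was lower and LXR targets were higher, which may reflect cells of each library differing in sterol load. If so, the means of the 2 lists should run against each other within a genotype. They did not do so detectably: Spearman's rho was 0.314 in wildtype and 0.20 in APOE-KO (two-sided exact p = 0.564 and 0.714, BH-adjusted p = 0.714 each over 4 relations), and Pearson's r 0.20 and 0.165 (exact p = 0.679 and 0.769). Without the 2 farthest libraries r was 0.323 and -0.405, so 6 libraries per genotype leave the question undecided.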
